A study of Rattus norvegicus with 8 samples.

How the data were processed

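Gene expression was measured in liver of male Sprague-Dawley rats, an outbred laboratory strain, on 8 Affymetrix arrays with 1 array for each combination of diet, treatment and time. Rats had been fed ethanol chronically or pair-fed a carbohydrate control diet. They were untreated or had been injected with AM21, an antisense oligonucleotide with locked nucleic acid (LNA) bases directed against the microRNA miR-21. AM21 was given intraperitoneally at 7.5 mg/kg, first 72 h before partial hepatectomy (PHx) and again right after it, per the labels' protocols. Liver was taken at the operation (0 h) and 24 h after removal of 70% of the liver. Per the labels' protocols, RNA of 3 animals (AM21) or 4 animals (untreated) was pooled before amplification and biotin labelling, so each array is 1 pool at 1 time.

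The deposited values are on a log2 scale. They had been made by the authors with RMA (background correction, normalization between arrays and summary per probe set) in Affymetrix Expression Console, per the submitters' processing notes; the versions are not given in the sources used here. On the 8 arrays the values ran from 0.481 to 13.3, with medians from 4.11 to 4.23. Arrays give no read depth, and the number of pools limits the precision. RMA fits all arrays together and brings their distributions close to each other, so a shift shared by most genes would not be seen.

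The platform table names 1 gene symbol for 18511 of the 36685 probe sets and several for 575; the other 17599 are unnamed here. Of the named probe sets, 18394 were found by their gene identifier in the GRCr8 RefSeq gene table, and 0 symbols needed an update. The array's genome build was not matched to that assembly, so no coordinates are given. They stand for 18166 genes, of which 291 have more than 1 probe set; the probe set with the highest mean over the 8 arrays then represented the gene. Genes with a mean log2 level of at least 5 were tested, which left 8690.

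The animal identifiers in the labels show that the same animals gave the 0 h and the 24 h tissue, so the 4 pools are matched pairs. Deviations of the 2 arrays of a pool from an additive fit of diet, AM21 and time correlated at -0.45, -0.62, -0.53 and -0.63 across genes. The additive fit by itself makes the deviations of the 2 arrays of a pool correlate negatively, also for independent arrays. Such residuals also hold any difference in response between the diets. The values therefore say nothing about the pairing, which rests on the identifiers. The AM21 and the untreated animals have separate ranges of identifiers, so treatment cannot be told apart from cohort. No oligonucleotide control group was analysed here.

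All fits used limma 3.58.1 in R 4.3.3 (lmFit, eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. The PHx response was the 24 h minus 0 h coefficient with the pool as a fixed block, which leaves 3 residual degrees of freedom. The diet effect (ethanol-fed minus pair-fed) and the AM21 effect (AM21 minus untreated) were averaged over the other factors in 1 additive fit, with the pool as a random block. The estimated consensus correlation within pools was -0.371 and was set to 0, as laid down in the design, so these fits treat the 8 arrays as independent although there were 4 pools. The interactions of PHx with diet and with AM21 were fitted with the pool as a fixed block and leave 1 residual degree of freedom. Differences between 2 single arrays have no replicate check. For them, the median of a gene list is given with its percentile among 10000 random lists matched on size and mean level.

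A total of 28 gene lists (pathways, cell type markers and literature targets of miR-21) were written before the data were examined. Of their 688 names, 609 had a probe set and 495 entries were tested. Each list was tested with camera at a preset correlation of 0.01, with an estimated correlation as an alternative, and with fry, a directional test of the list by itself. Adjusted p-values of lists are over the 28 lists. List tests of the interactions were added after the data had been seen.

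Genes were named by a rule fixed together with the lists. It took up to 10 rises and 10 falls per comparison among genes past the threshold that went the same way in all 4 matched pairs. A side with fewer than 5 was filled to 5 with the genes of the largest smallest-pair change, which did not pass. It also took up to 4 members per list, the 5 smallest p-values per interaction, the 5 largest rises and falls with AM21 in the ethanol-fed 24 h pair, and a fixed set of miR-21 and liver genes. Of that set, Btg2 had no probe set with a single name, and Adh1 is listed as Adh1c. Uncharacterised symbols were passed over. Probe sets of near-identical paralogs (Cyp2b1 and Cyp2b2, the glutathione transferases, the haemoglobin genes) can share signal and are uncertain as single genes.

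Every fit was first tested on simulated arrays of 8690 genes, with 50 genes changed at each of several known sizes. The PHx fit found 76% of changes of 0.58 on the log2 scale and 100% of those of 1 or more, with 20 false calls. The diet fit found 76% and 100% with 9 false calls, and the AM21 fit 74% and 100% with 12. The diet interaction found 16% at 0.58, 86% at 1 and 100% at 2, with 17 false calls, and the AM21 interaction 10%, 76% and 100% with 0. The diet and AM21 simulations drew independent arrays. Alternatives covered the level filter, the probe set rule, the scaling, the block, the prior, the time points, the list test and the omission of single arrays or pools. A planned test of miR-21 seed sites in 3' untranslated regions was not run, because no transcript sequences were used here. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.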

Results

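Liver RNA was profiled on 8 arrays that form 4 pools, each measured at 0 h and 24 h after PHx: pair-fed untreated, pair-fed AM21, ethanol-fed untreated and ethanol-fed AM21. Each group is 1 array, of RNA pooled from 3 or 4 rats, so the spread between animals was not measured. The study asked what miR-21 does while the liver regrows in animals fed ethanol chronically. Changes are given as log2 differences ± SE from the fit, over 4 matched pairs of arrays unless stated. The first principal component of the 8690 genes held 63.7% of the variance and separated the 0 h from the 24 h arrays. The second held 14.4% and had the 4 pair-fed arrays on one side and the 4 ethanol-fed arrays on the other.

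The first comparison asked how liver gene expression changed within a day of PHx. None of the arrays was of sham-operated rats, which undergo surgery but keep the whole liver. Changes with PHx, here and below, therefore cannot be told apart from effects of the surgery itself or of the time between samples. At 24 h the tested genes of DNA replication and mitosis were all higher than at 0 h, as were single acute phase genes, while single genes of lipid, drug and ethanol metabolism were lower. A2m, the major acute phase protein of the rat, rose 37.5-fold (5.23 ± 0.38, adjusted p = 0.00125), from a mean of 6.60 ± 1.40 to 11.83 ± 0.31 (SD, n = 4 arrays). Top2a, the topoisomerase of dividing cells, rose 15.0-fold (3.91 ± 0.46), and Lcn2, an iron-siderophore-binding acute phase protein, rose 12.8-fold (3.67 ± 0.26). The drug efflux pump Abcb1b rose by 3.60 ± 0.18. The other largest rises were in Ckap2, Cdk1, Pbk, Ccnb1, Mki67 and Rrm2, between 3.50 for Rrm2 and 3.89 for Ckap2, all genes of DNA synthesis or mitosis. Rgs16, a regulator of G protein signalling, fell by 3.99 ± 0.19 (adjusted p = 0.00039), and Inmt, an N-methyltransferase, fell by 2.94 ± 0.10. Stac3, best known as an adaptor of muscle calcium channels, fell by 3.60 ± 0.52. The remaining large falls were Cyp2b1 (-2.93), Cyp2b2 (-2.74), Nrep (-2.55), the zinc finger gene Zfp354a (-2.32), Serpina6, which encodes corticosteroid-binding globulin (-2.26), Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1 (-2.19), and the NADPH oxidase Nox4 (-2.17). RMA values carry no detection call, and for Ckap2, Cdk1, Pbk and Ccnb1 at 0 h, and Stac3, Inmt, Cyp2b1 and Nox4 at 24 h, the mean level was under the level minimum of 5, so the size of these changes is uncertain. The same holds among the genes named below for Gins1, S100a8, S100a9 and Gpx2 at 0 h and for Pnpla3 and Acacb at 24 h.

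All 24 tested genes of S phase and DNA replication rose after PHx, among them Mcm6 (2.89 ± 0.23), Gins1 (2.86 ± 0.25) and Mcm3 (2.48 ± 0.26), parts of the replicative helicase (camera adjusted p = 3.22e-16). All 25 tested genes of G2 and mitosis rose as well (camera adjusted p = 4.60e-15), with list medians of 2.96, 4.14, 1.79 and 2.43 in the pair-fed untreated, pair-fed AM21, ethanol-fed untreated and ethanol-fed AM21 pools. Of 12 genes of G1 and cell cycle inhibitors, 5 rose, with Cdkn2c at 2.03 ± 0.25 and Rbl1 at 1.95 ± 0.12 (camera adjusted p = 0.0137). Cdkn1a, the inhibitor p21, had a change of 1.39 ± 0.52 and did not pass (adjusted p = 0.0937). Ccnd1, cyclin D1, rose by 0.67 ± 0.12. Of 26 ribosome biogenesis genes 14 rose, or 16 adjusted over the list alone, such as Nhp2 (1.40 ± 0.14), Nop58 (1.18 ± 0.11) and Nop56 (1.14 ± 0.09), with a camera adjusted p of 7.55e-05. Of 24 acute phase genes 8 rose and 2 fell (9 and 2 adjusted over the list alone). Next to A2m and Lcn2 these included Lbp, the endotoxin-binding protein, at 1.16 ± 0.12, while the interleukin 6 receptor gene Il6r fell by 1.14 ± 0.16 (camera adjusted p = 0.00174). With an estimated correlation, none of the list calls passed (adjusted p = 0.341 for each of these 5 lists). By fry each of these 5 lists passed, with adjusted p between 0.00305 and 0.0187.

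Of the lists of hepatocyte functions, 6 were called lower at 24 h by camera. In fatty acid synthesis, 13 of 20 genes fell and 1 rose, led by the phosphatidate phosphatase Lpin1 (-2.09 ± 0.29), the liver pyruvate kinase Pklr (-1.95 ± 0.08), Pnpla3 (-1.88 ± 0.48) and Acacb (-1.73 ± 0.32). In fatty acid oxidation, 10 of 26 fell and 1 rose, including the peroxisomal enzyme Ehhadh (-1.81 ± 0.14), the receptor Ppara (-1.49 ± 0.16), the hormone gene Fgf21 (-1.29 ± 0.23) and Cpt1a (-1.12 ± 0.12), the gate of mitochondrial fatty acid import. In ethanol and aldehyde metabolism, 7 of 10 fell, such as Aldh1b1 (-0.69 ± 0.12), Aldh2 (-0.68 ± 0.10) and Aldh3a2 (-0.59 ± 0.09). Cyp2e1, the ethanol-inducible cytochrome P450, fell by 0.39 ± 0.09 (adjusted p = 0.0256; 0.0690 with no level filter), and the alcohol dehydrogenase Adh1c, at -0.19 ± 0.12, did not pass. Of 22 genes of the drug-metabolising P450 list, which also holds conjugating enzymes, the reductase Por and regulators, 10 fell and 2 rose. Adjusted over the list alone these were 12 and 3, with Cyp2c11 and Cyp2c23 each at -1.11. Of 16 bile acid genes, 7 fell and 2 rose (9 and 2 adjusted over the list alone), including the uptake transporter Slc10a1 (-1.18 ± 0.15), the nuclear receptor gene Nr0b2 (-1.17 ± 0.30) and Cyp27a1 (-1.07 ± 0.10). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a change of 0.57 ± 0.23 that did not pass (adjusted p = 0.118). Of 20 secreted hepatocyte proteins 4 fell and 1 rose, with Igfals at -1.14 ± 0.09, Plg at -0.44 ± 0.08 and Alb, albumin, at -0.04 ± 0.08, which did not pass. The camera adjusted p was 7.55e-05 for fatty acid synthesis, 9.14e-04 for oxidation, 1.15e-04 for ethanol metabolism, 3.00e-04 for P450s, 0.0132 for bile acids and 0.0160 for secreted proteins. With an estimated correlation it was 0.341 for each. By fry all 6 lists passed, with adjusted p between 0.00305 and 0.0195.

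Markers of other liver cells moved alongside. S100a8 and S100a9, abundant in neutrophils, rose by 3.09 ± 0.37 and 2.01 ± 0.32, and 3 of 6 neutrophil and monocyte markers rose. Timp1, the tissue inhibitor of metalloproteinases made by activated stellate cells among others, rose by 2.61 ± 0.23. In that stellate and fibroblast list 10 of 22 rose and 4 fell, among them Lrat of quiescent stellate cells (-0.96 ± 0.17). Of 22 Kupffer cell and macrophage markers, 1 rose (Marco, 1.06 ± 0.10) and 4 fell, such as Clec4f (-0.66 ± 0.14). Sinusoidal endothelial markers included 5 falls, with Ehd3 and Oit3 at -0.73 each, and 3 rises among 15 genes. In the cholangiocyte and progenitor list 3 of 8 genes rose and 1 fell, with Krt18, which is not specific to these cells, at 1.26 ± 0.27. Of 26 lymphocyte markers 23 had a probe set and only 3 reached the level minimum, so most of that list was not tested. Of these 3 markers 2 fell, Ccl5 (-0.97 ± 0.09) and Cd4 (-0.42 ± 0.10). Camera called the lymphocyte list lower (adjusted p = 0.0348, and 0.341 with an estimated correlation) and none of the other 5 of these lists. Fry called the lymphocyte (adjusted p = 0.00305) and endothelial (0.0104) lists lower and the stellate list higher (0.0092).

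Among stress and signalling lists, the 15 clock genes were called lower, with 4 falls that include Bhlhe40 (-0.98 ± 0.17) and Tef (-0.81 ± 0.21) (camera adjusted p = 0.0372; adjusted p = 0.348 with an estimated correlation). The rest of the lists were not called by camera, although single members changed. Of these, fry called the miR-21 target (adjusted p = 0.0197) and urea cycle (0.0092) lists lower. It called the oxidative stress (0.0092) and immediate early (0.0305) lists higher. In the oxidative stress list, where 6 of 21 rose and 3 fell (6 and 4 adjusted over the list alone), Gpx2 rose by 2.31 ± 0.12 and Nqo1 by 2.15 ± 0.09. In the unfolded protein response 8 of 22 rose and 2 fell (9 and 4 adjusted over the list alone), with Sdf2l1 at 0.94 ± 0.08 and Herpud1 at -0.94 ± 0.12. Of 14 immediate early genes 4 rose and 2 fell (5 and 2 adjusted over the list alone), with Dusp1 at -1.92 ± 0.14 and Socs3 at 1.08 ± 0.16. Of 18 cytokine, growth factor and matrix genes 6 rose and 3 fell (7 and 3 adjusted over the list alone), with Cxcl1 at 1.53 ± 0.42 and Igfbp3 at -1.37 ± 0.13. Of 15 p53 targets 4 rose and 2 fell, with Ccng1 at 1.07 ± 0.19 and Xpc at -0.98 ± 0.17. Of 27 interferon response genes 1 rose and 4 fell (1 and 3 adjusted over the list alone), with Cxcl9 at -1.57 ± 0.17. Of 22 genes of the urea cycle, gluconeogenesis and amino acid breakdown 7 fell and 2 rose, with Sds at -1.60 ± 0.32. Of 27 literature targets of miR-21, 9 fell and 3 rose (11 and 4 adjusted over the list alone), among them Ppara (-1.49), Sesn1 (-0.92 ± 0.17), Pdcd4 (-0.83 ± 0.10), Cdc25a (0.86 ± 0.15) and Stat3 (0.83 ± 0.10). No member of the cholesterol synthesis list (19 genes) or of the erythroid list (5 genes) passed, also when adjusted over the list alone. In the lists above with no separate count, the numbers adjusted over the list alone equal those over all genes.

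In all, 2443 of 8690 genes changed with PHx, 1330 up and 1113 down, and 2430 of them went the same way in all 4 pools. Among all 8690 genes 48.98% did so. The test favours genes whose pools agree, so this agreement is not separate support. A change of at least 2-fold in every pool was seen in 217 genes, 164 up and 53 down. The change correlated between pools across genes with r from 0.718 to 0.809 (genes are not independent replicates). The count was 1466 without the ethanol-fed AM21 pool, 1566 without the ethanol-fed untreated pool, 1628 without the pair-fed AM21 pool and 1705 without the pair-fed untreated pool.

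**Figure D1:**
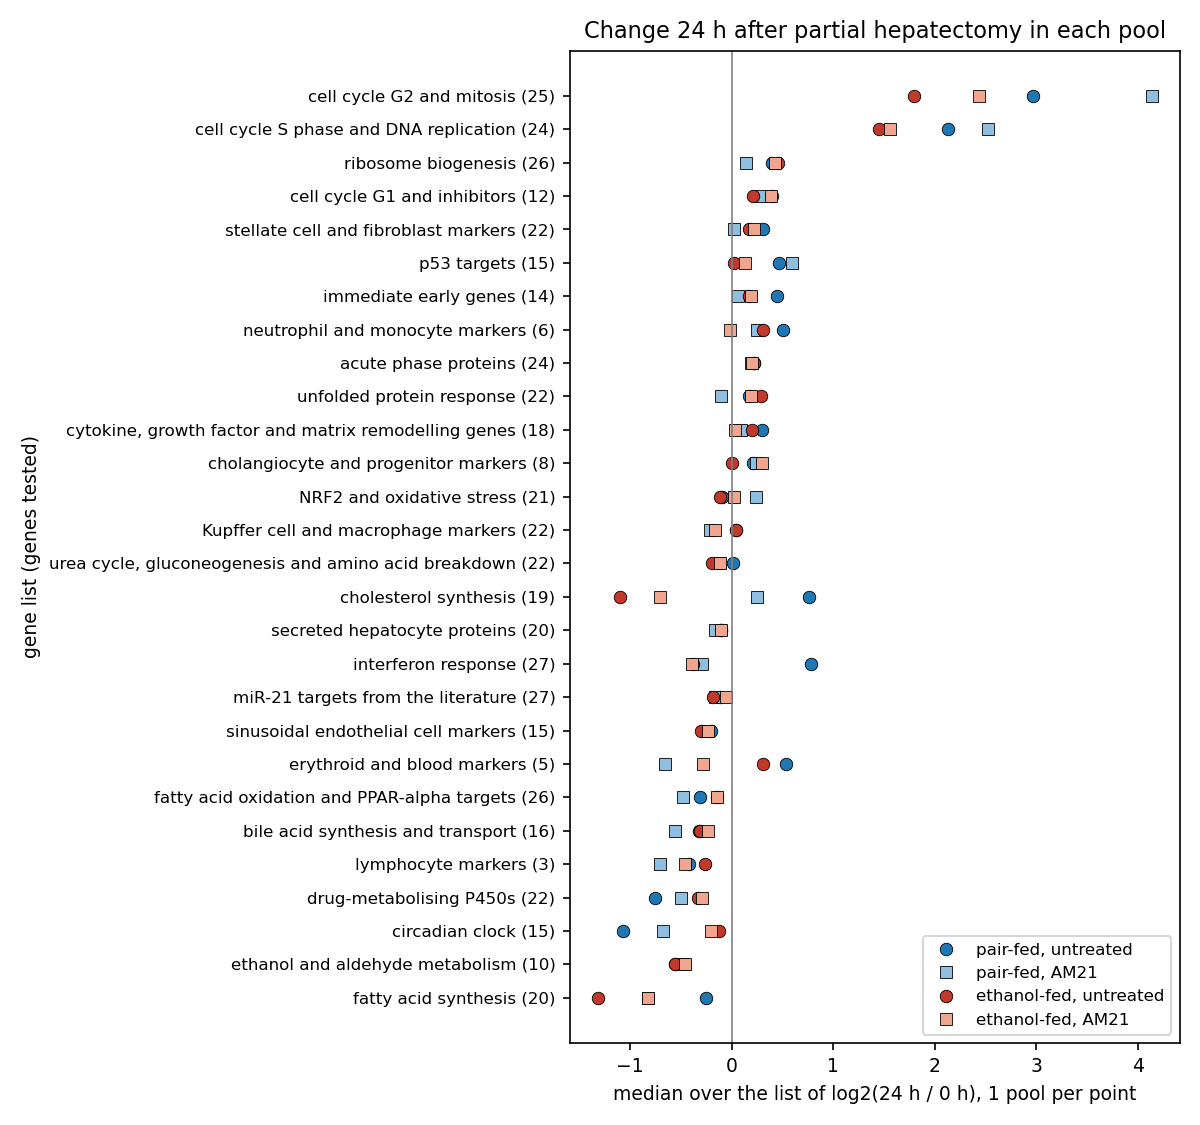
Median log2 change from 0 h to 24 h after PHx (horizontal axis) in each of the 28 gene lists (vertical axis, with the number of genes tested), with 1 point per pool coloured by diet and treatment. The mitotic list lies between 1.79 and 4.14 in the 4 pools, and the cholesterol synthesis list is above 0 in both pair-fed pools and below 0 in both ethanol-fed pools.

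The second comparison asked what chronic ethanol feeding changed, averaged over treatment and time. Single genes that act on aldehydes, drugs and fatty acids, and single macrophage markers, were higher in ethanol-fed livers. Gsta3, a glutathione transferase, had a mean level of 7.07 ± 0.60 in ethanol-fed and 3.85 ± 0.62 in pair-fed livers (SD, n = 4 arrays each; fitted difference 3.23 ± 0.33, adjusted p = 0.0139). Cyp2b1, a drug-inducible P450, was higher by 2.90 ± 0.34 and the carboxylesterase gene Ces2e by 1.98 ± 0.25. The pair-fed means of Gsta3, Cyp2b1, Ces2e and Abcc3 and the ethanol-fed means of Spin2b and Reg4 were under 5, not shown to be above background, so the size of these differences is uncertain. Aldh1a1, which oxidises acetaldehyde and retinal, was 2.81-fold higher (1.49 ± 0.11, adjusted p = 0.00766). Also higher were the prolactin receptor Prlr (1.81), the acyl-CoA synthetases Acsf2 (1.53) and Acsm5 (1.49), the bile salt and conjugate exporter Abcc3 (1.48), the endotoxin co-receptor Cd14 (1.24) and Trib3, a pseudokinase of the stress response (1.11). Car3, an abundant carbonic anhydrase of male rat liver, was lower by 2.34 (fitted change -2.34 ± 0.19, adjusted p = 0.0112). The other 6 genes that fell were Spin2b (-1.78), Hsd17b2 (-1.64), Fam111a (-1.48), Cdh17 (-1.32), Reg4 (-0.90) and Isg20 (-0.90). Of the fixed set of named genes, 2 belong to ethanol metabolism. Cyp2e1 RNA differed by 0.00 ± 0.11 and Adh1c RNA by 0.12 ± 0.11, and neither passed. Protein was not measured, so these values do not check the exposure.

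**Figure D2:**
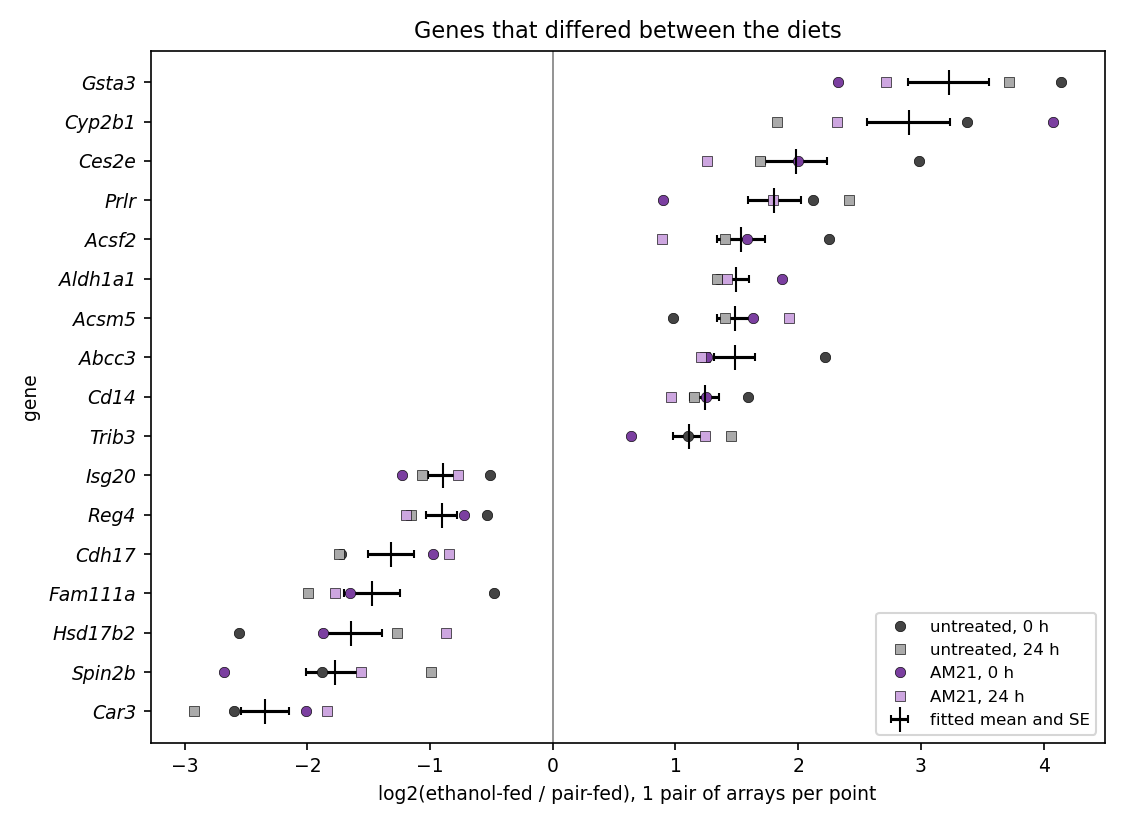
Log2 ratio of ethanol-fed to pair-fed liver (horizontal axis) for the 17 named genes past the threshold, with 1 point per pair of arrays at the same treatment and time, and the fitted mean with its SE. The naming rule took only genes whose 4 pairs lie on the same side of 0. The values run from -2.92 for Car3 to 4.15 for Gsta3.

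Macrophage and Kupffer cell markers had list medians of 0.44, 0.40, 0.41 and 0.40 in the 4 pairs. Marco (0.77 ± 0.10) and Cd5l (0.71 ± 0.09) passed over all genes, and 18 of 22 passed adjusted over the list alone (camera adjusted p = 1.75e-13; adjusted p = 0.157 with an estimated correlation). Of 26 genes of fatty acid oxidation and targets of PPAR-alpha 3 rose, or 13 adjusted over the list alone (camera adjusted p = 4.39e-10; adjusted p = 0.157 with an estimated correlation). Of these, Ehhadh was higher by 1.08 ± 0.14 and Cyp4a1, a fatty acid hydroxylase, by 0.95 ± 0.14, while Pdk4 (1.04 ± 0.26) and Vnn1 (1.01 ± 0.19) did not pass. In ethanol and aldehyde metabolism 2 of 10 rose, Aldh1a1 and Adh6 (0.97 ± 0.09). The camera call included the lists of the urea cycle and amino acid breakdown (0 of 22, 6 adjusted over the list alone; Igfbp1 at 1.56 ± 0.41 did not pass), sinusoidal endothelial cells (0 of 15 and 4; Cdh5 0.45 ± 0.09), oxidative stress (1 of 21, Gsta3, and 6), bile acids (1 of 16, Abcc3, and 7 higher with 1 lower), P450s (2 of 22 and 6 higher with 1 lower) and neutrophils and monocytes (0 of 6 and 2; Cybb 0.58 ± 0.11). The S phase list was called lower (0 of 24; camera adjusted p = 0.0253). Its pair medians went both ways, 0.38 and 0.14 at 0 h and -0.34 and -0.63 at 24 h. With an estimated correlation none of the 10 list calls passed. The adjusted p was 0.157 for the macrophage, fatty acid oxidation, ethanol, urea cycle, endothelial and oxidative stress lists, 0.186 for P450s, 0.476 for bile acids, 0.565 for neutrophils and 0.888 for S phase.

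Of 8690 genes, 40 differed between the diets, 33 higher and 7 lower in ethanol-fed liver, and each went the same way in all 4 pairs. Among all 8690 genes 24.03% did so. The test favours genes whose pairs agree, and the 0 h and 24 h pairs come from the same pools. This agreement is therefore not separate support. At an unadjusted p under 0.05 there were 1335, where 434.5 would be expected by chance. The count depended on single arrays. Without the pair-fed untreated 24 h array 0 genes passed, without the pair-fed untreated 0 h array 5, without the ethanol-fed AM21 24 h array 7, and without any of the other 5 arrays between 12 and 18. With the 24 h arrays alone 0 passed and with the 0 h arrays alone 101. It was 11 without the level filter, and 285 in a model with all 2-way interactions.

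The third comparison asked whether the response to PHx depended on the diet. A smaller rise in ethanol-fed pools passed the test in 14 of 25 mitotic genes and 1 of 24 S phase genes. Ccnb1, cyclin B1, differed between 24 h and 0 h by 4.06 and 5.53 in the pair-fed pools and by 1.99 and 2.72 in the ethanol-fed pools (difference -2.44 ± 0.24, adjusted p = 0.00971). The levels of Ccnb1 at 0 h were 4.04 and 3.73 in pair-fed and 5.70 and 5.26 in ethanol-fed liver, and at 24 h 8.10 and 9.27 against 7.69 and 7.98. Its pair-fed 0 h levels were not shown to be above background, so the size of this difference is uncertain. Cdkn1a gave the smallest p (-2.66 ± 0.21, adjusted p = 0.00522): it rose by 2.86 and 2.57 in the pair-fed pools, and the changes in the ethanol-fed pools were 0.02 and 0.09, from 0 h levels of 8.38 in both. Cdkn3, a phosphatase of the cell cycle, and Cyp2c55, a P450, also rose less in ethanol-fed pools (-2.23 ± 0.20 and -2.54 ± 0.21). Stac3 differed by 2.56 ± 0.20, but its 24 h levels were under 5 in all pools, so a smaller fall in ethanol-fed pools, which started at 5.67 and 5.61 against 8.83 and 8.93, is not shown. Lox, the collagen cross-linking enzyme, had differences of -0.60 and -0.84 in pair-fed and of 1.49 and 1.39 in ethanol-fed pools (difference 2.16 ± 0.20, adjusted p = 0.00809). Cyp2c55 in pair-fed and Lox in ethanol-fed liver were under 5 at 0 h, so the size of these differences is uncertain.

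Of 25 mitotic genes 14 had a smaller rise in ethanol-fed pools, or all 25 adjusted over the list alone, with a median difference of -1.54 (camera adjusted p = 1.25e-36). Of 24 S phase genes 1 passed, Rrm2, and 19 adjusted over the list alone (median -0.70). Of 19 cholesterol synthesis genes 8 passed, and all 19 adjusted over the list alone (median -1.63, camera adjusted p = 2.01e-28). Sqle, squalene epoxidase, differed by -2.57 ± 0.27, Idi1 by -2.36 ± 0.24 and Dhcr7 by -2.07 ± 0.23. Clock genes had a positive difference (median 0.64), with 2 of 15 past the threshold, Per2 (1.93 ± 0.21) and Usp2 (1.65 ± 0.23). Interferon response genes had a negative one (median -0.64), with Ifit1 at -2.65 ± 0.38 (under 5 at 24 h in both ethanol-fed pools) and Isg15 at -1.91 ± 0.30. Isg15 stood at 9.57 in the pair-fed untreated 24 h array and between 6.78 and 7.80 in the other 7 arrays. The interferon list differed by a median of -1.04 in the untreated and -0.17 in the AM21 cohort. With an estimated correlation, the adjusted p of each of these 5 lists was 0.839. These list tests were added after the data had been seen.

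In total 46 genes differed in their PHx response between the diets, 40 with a negative and 6 with a positive difference. With 1 residual degree of freedom, the count was 16 at a minimum level of 6, and 0 without the level filter or after quantile normalization. Of the 40, 25 were among the 1330 genes that rose with PHx, where 6.12 would be shared by independent lists. The PHx response and this difference come from the same arrays, so part of the overlap may be shared error.

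**Figure D3:**
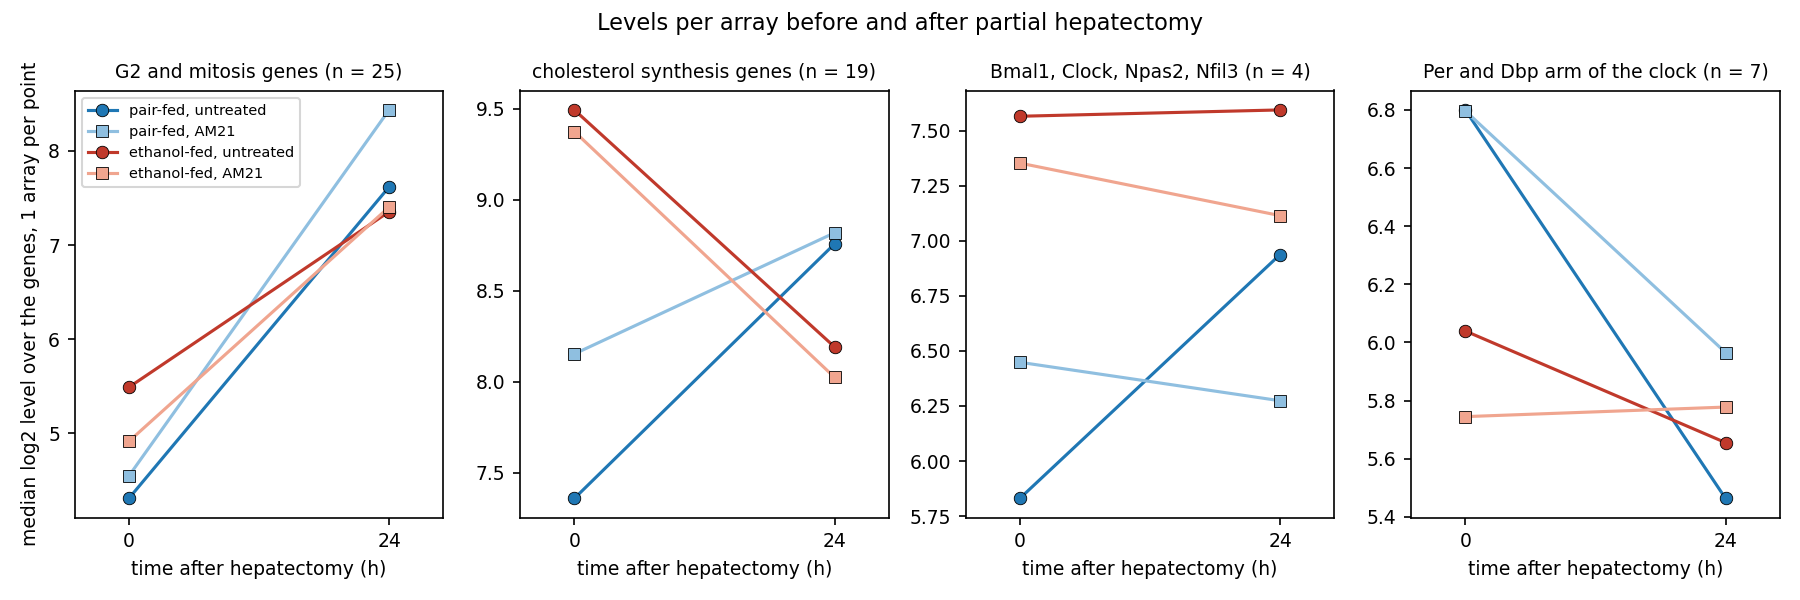
Median log2 level (vertical axis, scaled separately in each panel) of 4 gene sets at 0 h and 24 h after PHx (horizontal axis), with 1 line per pool and 1 array per point. Mitotic genes started at 4.31 and 4.55 in pair-fed and at 5.49 and 4.91 in ethanol-fed liver, and cholesterol synthesis genes at 7.36 and 8.15 against 9.49 and 9.37.

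The fourth comparison asked what the miR-21 antisense oligonucleotide changed. No gene passed the threshold for a difference between AM21 and untreated livers averaged over both diets and times. Mir21 itself has a probe set, which reads its transcript and not the mature microRNA that AM21 binds, so it does not check the inhibition. Its levels at 0 h were 6.17 in untreated against 5.16 in AM21 pair-fed liver and 5.53 against 4.93 in ethanol-fed liver, and at 24 h 4.94 against 4.53 and 4.74 against 4.80 (named because it is the target, outside the rule). The mean difference over the 4 pairs was -0.49 and did not pass. Of the 8 levels 5 are under 5 and not shown to be above background. Only the pair-fed 0 h pair had both levels above 5, and it is 1 array against 1, so no difference in Mir21 is established. In each pool the level was lower at 24 h than at 0 h, but all 24 h levels were under 5. The host gene Vmp1 differed by -0.19 ± 0.11. Of 27 literature targets of miR-21 0 passed (camera adjusted p = 0.515, with an upward direction although the fitted median was -0.04), with list medians of 0.00, -0.05, -0.02 and 0.08 in the pair-fed 0 h, pair-fed 24 h, ethanol-fed 0 h and ethanol-fed 24 h pairs. Among them, Timp3 was higher in 4 of 4 pairs (0.33 ± 0.10, adjusted p = 0.759), as was Pik3r1 (0.33 ± 0.12). Of all 8690 genes, 15.58% went the same way in all 4 pairs. The tumour suppressor Pdcd4 differed by 0.08 ± 0.10, Spry1 by -0.04 ± 0.08, Reck by -0.01 ± 0.11, Tpm1 by -0.15 ± 0.12 and Crim1 by 0.05 ± 0.09.

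The genes whose smallest difference over the 4 pairs was largest, none of which passed, were Tmem125 (0.70 ± 0.08, adjusted p = 0.310), Nrep (0.84), Mir761 (0.76), Mir3597-1 (0.76) and the olfactory receptor gene Or52l1 (0.68) on the higher side. On the lower side they were Timd4, a receptor of resident macrophages (-0.71 ± 0.12), Ugt2b34l1 (-0.70), Mocos (-0.83), A2m (-1.37 ± 0.36) and Cyp2b1 (-0.99 ± 0.34). The pair-fed mean of Cyp2b1 was under 5, so the size of its difference is uncertain. A2m was lower with AM21 in 4 of 4 pairs, as the naming rule required. Its differences were -2.69 and -1.70 at 0 h and -0.60 and -0.49 at 24 h in pair-fed and ethanol-fed liver. Camera called 9 lists, 7 higher and 2 lower. The fatty acid synthesis list was highest (median 0.26, adjusted p = 1.86e-07, with 0 of 20 genes past the threshold and 3 adjusted over the list alone; Elovl5 0.55 ± 0.13). Its pair medians were 0.56, 0.16, -0.09 and 0.14. The S phase, G2 and mitosis, ethanol metabolism, fatty acid oxidation, cholesterol and sinusoidal endothelial lists were also called higher, with medians from 0.02 to 0.13, and the stellate (-0.11) and neutrophil (-0.20) lists lower. The G2 and mitosis pair medians went both ways, -0.20 and -0.44 at 0 h and 0.97 and 0.14 at 24 h in pair-fed and ethanol-fed liver. None of the 9 lists was called with an estimated correlation (adjusted p = 0.625 for fatty acid synthesis and between 0.620 and 0.735 for the others) or by fry. Calls depended on the filter and the scaling: 2 lists without the level filter, 5 at a level of 6 or more, 4 higher and 4 lower after quantile normalization, and 6 higher and 4 lower after median centring.

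With limma, 0 of 8690 genes passed for AM21. At an unadjusted p under 0.05 there were 538, 124 higher and 414 lower, against 434.5 expected by chance. The median AM21 difference over all genes was -0.03, and it was -0.002 after quantile normalization and 0.001 after median centring. How much of the excess on the lower side is such a shared shift was not tested. A model with all 2-way interactions called 8. The AM21 difference correlated across genes between pairs with r from -0.04 to 0.27, the highest between the pair-fed and ethanol-fed 24 h pairs. Treatment and cohort cannot be told apart in these samples. The average over times also mixes tissue from before and after the repeated AM21 injection.

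In the ethanol-fed liver at 24 h, the setting the study was built on, AM21 can be compared with no treatment as 1 array against 1, with no test. The largest rises were in Abhd3, a phospholipid hydrolase (2.28), the clock repressor Nr1d1 (1.74), Cyp2b2 (1.59), Nrep (1.47) and Mgp, matrix Gla protein (1.28). Abhd3 and Nr1d1 were also higher in the ethanol-fed 0 h pair (1.87 and 1.76), although Abhd3 was under 5 in both untreated arrays. The largest falls were in Hba-a3 (-2.68), a haemoglobin gene, Rgs16 (-1.66), Syne4 (-1.56), Ces2e (-1.54) and the neuropeptide gene Npy (-1.53). The mitotic list had a median of 0.14 in this pair, with 22 of 25 genes higher (percentile 99.9 among random lists), and of 0.97 in the pair-fed 24 h pair, with 25 of 25 higher (percentile 100). Genes of this list move together and random lists do not, so these percentiles describe the arrays and test nothing.

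The interaction of AM21 with PHx gave 0 genes past the threshold with limma, 604 at an unadjusted p under 0.05 and a smallest adjusted p of 0.161. AM21 was injected again right after PHx, so the 0 h tissue had only the first injection. The interaction cannot be told apart from an effect of that repeated dose. The genes with the smallest p were Cyp2b2 (2.20 ± 0.26), the aldose reductase family gene Akr1b7 (1.79 ± 0.22), Cyp2c55 (-1.50 ± 0.21), the haemoglobin gene Hbb-b1 (-1.46 ± 0.20) and the spindle gene Aspm (1.35 ± 0.20). Hbb-b1 stood at 10.83 and 10.86 in the untreated 24 h arrays and at 9.52 and 9.48 in the AM21 ones. At 0 h Aspm was under 5 in all pools, and Akr1b7 and Cyp2c55 in both pair-fed pools. Camera called the mitotic list higher (median 0.94, 21 of 25 adjusted over the list alone, adjusted p = 4.19e-33), with a difference of 1.18 in pair-fed pools (25 of 25 genes) and 0.62 in ethanol-fed pools (23 of 25). Part of it lay at 0 h, where the AM21 medians of the list were -0.20 and -0.44 in pair-fed and ethanol-fed liver. At 24 h they were 0.97 and 0.14, so in ethanol-fed liver the larger part lay at 0 h. In ethanol-fed liver the list levels were 4.91 with AM21 and 5.49 without at 0 h, and 7.40 and 7.36 at 24 h. In pair-fed liver the 0 h levels were 4.55 with AM21 and 4.31 without. All of these 0 h levels but 5.49 were under 5, so the size of the 0 h part is uncertain. The S phase (0.32) and P450 (0.19) lists were also called higher. The erythroid (-0.79), neutrophil (-0.44), interferon (-0.36) and macrophage (-0.25) lists were called lower. The interferon difference lay in the pair-fed pools (-0.76, against 0.03 in ethanol-fed pools), where the PHx median of the list was 0.78 in the untreated and -0.29 in the AM21 pool. For each of these lists the adjusted p was 0.803 with an estimated correlation.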

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

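The list tests of both interactions, and the tests of the mitotic and clock patterns below, were chosen after those results had been seen. With 1 array per group, no array was tested as an outlier.

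A difference in the PHx response between the diets passed the interaction test in 46 genes. Named genes that rose less in ethanol-fed pools were Top2a (-1.96), Ckap2 (-2.25), Cdk1 (-1.99), Pbk (-2.05), Ccnb1 (-2.44), Mki67 (-1.75), Rrm2 (-2.19), Cdkn1a (-2.66), Cdkn3 (-2.23) and Cyp2c55 (-2.54). Cyp2b1 differed by -1.66 and Stac3 by 2.56, but the pools with the smaller fall ended under the level minimum of 5 at 24 h, so a difference in response is not shown for either. Lox differed by 2.16. At 0 h Ckap2, Cdk1, Pbk, Ccnb1, Mki67 and Cyp2c55 were under 5 in both pair-fed pools and Lox in both ethanol-fed pools, so these sizes are uncertain. Lists with a negative difference were G2 and mitosis (-1.54), cholesterol synthesis (-1.63), S phase (-0.70), interferon response (-0.64), fatty acid synthesis (-0.51) and p53 targets (-0.49). Those with a positive one were the clock (0.64), bile acid (0.22) and fatty acid oxidation (0.19) lists. With an estimated correlation none of these list calls passed (adjusted p = 0.839 for each), and none passed with fry.

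The mitotic list is the first pattern: in the cohort with the smaller difference, the untreated animals, the median over its genes was -1.18 with a median absolute deviation of 0.62 over genes, and 25 of 25 genes were lower. The difference was thus seen in both cohorts, but each compares 1 pool with 1 pool. Genes of this list move together, so the deviation over genes is not the spread between pools. The PHx medians of the 2 pair-fed pools also differed from each other (2.96 and 4.14), so a spread between pools is not excluded. The difference between the diets has 2 parts. At 0 h the list was higher in ethanol-fed liver by 0.73, with 20 of 25 genes higher in both cohorts. At 24 h it was lower by 0.76, with 25 of 25 lower in both. The 0 h median levels of 4.31 and 4.55 in pair-fed and 4.91 in ethanol-fed AM21 liver were under the level minimum of 5. The size of the 0 h part is therefore uncertain. Cycling immune cells in the ethanol-fed liver are a candidate explanation of the 0 h part. The highest of the macrophage, lymphocyte and neutrophil lists was 0.41 higher at 0 h, above 0 but below the 0.73 of the mitotic list, so this stays open, as do an effect of ethanol on hepatocytes and a shift in the timing of division, which a single time after PHx leaves untested.

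The clock list is the second pattern: at 0 h the Bmal1 arm (Bmal1, Clock, Npas2, Nfil3) was higher and the arm with the Per genes and Dbp lower in ethanol-fed liver, with a gap between the arms of 2.41 in untreated and 2.07 in AM21-treated animals. At 24 h the gaps were 0.17 and 0.85. A different clock phase at tissue collection is a candidate explanation, which stays open, because the gap of 2.07 restates the difference that prompted it. Whether the phase differed through the hour of collection, feeding times or ethanol itself was not tested, since the labels used here give no hour.

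For the PHx response with AM21, camera called the lists G2 and mitosis (0.94), S phase (0.32) and P450s (0.19) with a positive difference. Part of the mitotic difference lay at 0 h, in ethanol-fed liver the larger part, at levels mostly under the minimum. Those with a negative one were erythroid (-0.79), neutrophil and monocyte (-0.44), interferon (-0.36) and macrophage (-0.25) markers. The interferon difference was -0.76 in pair-fed and 0.03 in ethanol-fed pools, and both it and the diet difference of that list lay with the pair-fed untreated pool, whose PHx median was 0.78 against -0.39 to -0.29 in the others. With an estimated correlation none of these calls passed (adjusted p = 0.803 for each), none passed with fry, and no member passed over all genes. An effect of the AM21 injection repeated right after PHx cannot be told apart from these differences. The oxidative stress list moved opposite ways after PHx in the AM21 and the untreated pools, by a difference of 0.24 between the mean list medians. This difference was called opposite without a test, and the list's PHx median changes sign with the scaling. Among 4218 probe sets with no single gene name, which no comparison above used, 172 changed with PHx.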

How the results depend on the processing

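The list tests of the interactions and the fit with the consensus correlation as estimated were chosen after seeing the data. The cause of each shift was not tested, except that fewer arrays or genes were used where stated. Under the 5 alternatives of filter, probe set rule and scaling alone, 589 of 626 values of named genes kept their side of the threshold. Of the others, 37 no longer passed and 0 newly passed. Direction was compared only where the main fit or the alternative passed, and there 0 reversed. Values that passed in neither count as kept, whatever their direction. Of 13 named diet by PHx genes 0 passed with no level filter or after quantile normalization. After quantile normalization the median diet by PHx difference was -1.37 for the mitotic list and -1.58 for the cholesterol list (-1.54 and -1.63 in the main fit). In fits of fewer arrays, of 17 named diet genes 0 passed without the pair-fed untreated 24 h array or with the 24 h arrays alone, 12 with the 0 h arrays alone and between 5 and 9 without any 1 of the other arrays. Of 23 named PHx genes 22 or 23 passed without 1 pool. None changed sign in these fits. The diet count of 40 became 11 with no level filter, 86 with an intensity trend and robust prior, 102 with pool means, 285 with all 2-way interactions, 101 with 0 h arrays alone, 0 with 24 h arrays alone and 661 with the correlation as estimated. Leaving out 1 array gave between 0 and 18. The AM21 count of 0 became 8 with all 2-way interactions and 1 with the correlation as estimated. The diet by PHx count of 46 became 0 with no filter, 16 at a level of at least 6 and 0 after quantile normalization. Leaving a pool out of the interaction fits leaves no residual degrees of freedom. The PHx count was 2702 with no replicate block (pairing by pool) but with diet and AM21 in the fit, against 2443 with the block, and between 1466 and 1705 without 1 pool. For diet and AM21 the correlation within pools was set to 0, so a fit with no block is the same fit and tests nothing. Lists called fell to 0 with an estimated correlation in all 5 comparisons (PHx 13, diet 10, AM21 9, diet by PHx 9, AM21 by PHx 7), and to 0 by fry for AM21 and both interactions. Fry called all of the 13 PHx lists but the clock list (fry adjusted p = 0.0829). It also called PHx lists that camera did not. These were lower for the miR-21 target (0.0197), urea cycle (0.0092) and endothelial (0.0104) lists. They were higher for the oxidative stress (0.0092), stellate (0.0092) and immediate early (0.0305) lists. Of the 10 diet lists fry called all but the bile acid (0.154), neutrophil (0.192) and S phase (0.795) lists. Outside those 10 it called the acute phase list higher with diet (0.0119). AM21 lists called by camera were 2 with no filter and 5 at a level of at least 6. By size alone, PHx genes over 2-fold in all pairs were 217, 135 at a level of at least 6 and 528 over 1.5-fold. Diet genes over 1.5-fold were 40, and 234 over 1.2-fold. AM21 genes over 1.5-fold were 1, with 3 under no filter, 0 at a level of at least 6, 2 after quantile normalization, 2 after median centring and 39 over 1.2-fold. The miR-21 seed site test and its alternatives were not run. Dim genes near the array background limit small differences.

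Other splits of the 8 arrays into 4 and 4 tested whether chance could give the counts. For PHx in a fit of time alone, with no pool, diet or AM21 term, 1 of 35 splits, the real one, gave as many as its 2422 genes and the highest other gave 1. For diet, 1 of 33 gave as many as 40 and the highest other 0. For AM21 the real count is 0, so all 33 of 33 gave as many by construction, with a highest other of 5. These splits treat the 2 arrays of a pool as independent. Only 8 splits part every pool for PHx (1 of them, the real one, with 2443 genes, and a highest other of 0), and only 3 keep the pools whole for diet or AM21, too few for a share under 0.05.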

Other observations

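The test of the olfactory receptor probe sets below was set before its result was seen; the remaining values were picked after the data had been examined.

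The interferon genes Mx2, Isg15, Irf7 and Ifit1 were high in 1 array only, the pair-fed untreated 24 h pool. Mx2 stood at 9.50 there and between 6.05 and 7.05 in the other 7 arrays, Irf7 at 7.72 against at most 6.41, and Ifit1 at 6.94 against at most 5.98. In that pool the interferon list had a median PHx difference of 0.78, while the 3 other pools had medians between -0.39 and -0.29. Leaving out this array also left no diet calls, as did using the 24 h arrays alone, and leaving out any other array lowered the count. Whether the interferon genes bear on this was not tested. A few genes of blood cells, picked for their values and not past the AM21 threshold, were lower in both AM21 24 h arrays than in the untreated ones. S100a8 was at 6.42 and 7.42 with AM21 against 8.09 and 8.54 without, S100a9 at 5.82 and 6.42 against 7.87 and 7.54, and Hba-a1 at 10.51 and 10.30 against 11.27 and 11.08. Fabp4, a fatty acid binding protein of fat cells, macrophages and endothelium, was at 6.46 and 7.11 against 8.05 and 8.48. At 0 h the erythroid list had AM21 medians of 0.28 and 0.12, the other direction, and the lymphocyte list had medians of 0.01 and 0.04 at 24 h.

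Cholesterol synthesis genes crossed over between the diets. In both cohorts 19 of 19 were higher in ethanol-fed liver at 0 h, and 18 of 19 were lower at 24 h. Single pair medians at 0 h were 1.28 in untreated and 0.57 in AM21-treated animals.

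Of the 5 genes named for a rise with AM21 in all 4 pairs, 2 were microRNA genes and 1 an olfactory receptor gene, which liver is not known to use, and a difference in array background between the cohorts is a candidate explanation. The 28 olfactory receptor genes at a level of 5 or more had a median AM21 change of 0.21 with a median absolute deviation of 0.31, and pair medians of -0.07, 0.24, 0.21 and 0.16. Over all 1185 olfactory receptor genes, with a median level of 2.61, the median change was 0.07, with pair medians of 0.05, 0.16, 0.01 and 0.05. The 36 microRNA genes at a level of 5 or more had a median of 0.14 and the other 8626 genes one of -0.03. Among the 28 genes the pair-fed 0 h pair had no rise, while over all 1185 every pair median was above 0, so the values leave the explanation open, and it cannot be told apart from a cohort effect.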
